A study of Mus musculus with 35 samples.

How the data were processed

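Methylation was measured in LSK cells sorted from mice, in 35 libraries of 9 groups. Per the labels' protocols, DNA was cut with MspI, selected by fragment size, bisulfite-converted and then amplified by PCR. Genome build mm9 and CASAVA 1.8.2 are named, per the submitters' processing notes. The aligner and the methylation caller are not given in the sources used here. Per the file headers, each deposited table gives, for a CpG position on one strand, the coverage as a read count, and the percent of those reads with C (methylated) and with T (unmethylated). The deposited positions start at a coverage of 10. Methylated reads were recovered as coverage times the percent of C, which came within 0.02 reads of a whole number at 99.975 to 99.9864% of positions per library. Libraries held 126816062 to 280335200 reads summed over positions. PCR reads without molecular identifiers are not independent molecules, so the test takes its error from the spread between libraries.

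Groups and replicate numbers were taken from the sample labels. Nothing there says that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. The series design text adds the name decitabine in brackets to 5-azacytidine; these are different drugs, and the name in the treatment protocol, 5-Aza, was used. The file names carry 6 prefixes, treated as possible batches. Wild type has its own. IDH2 vehicle and AG-221 share one, and so do IDH2 AC220 and the IDH2 combination. TET2 vehicle replicates 1 to 4 share one with TET2 AC220, and replicates 5 and 6 with TET2 5-Aza. The TET2 combination has its own. Chromosome Y coverage was found in 25 libraries (314 to 601 positions). In the other 10 (8 to 108 positions) it was taken as lacking, with a threshold of 200: all IDH2 AC220 and IDH2 combination libraries, TET2 vehicle replicates 3 and 4 and TET2 AC220 replicates 2 and 4.

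The tests, the samples in each, the other settings to be tried and the rule for named tiles were fixed before the data were examined. The 1101719 positions on the 19 autosomes with a coverage of at least 10 in all 35 libraries were used, and the 78870 tiles of 1 kb with at least 3 such positions were tested. Methylated and unmethylated reads were summed per tile and fitted with a quasi-binomial logistic model of the 2 groups compared. The Pearson dispersion was moderated across tiles with squeezeVar of limma 3.58.1 in R 4.3.3 and kept at 1 or more, and p-values were adjusted by the Benjamini-Hochberg method. A tile was called at an adjusted p under 0.05 and a difference of group means of at least 10 percentage points. The test was tested on simulated data with the coverage, levels and spread of each comparison, in which 100 tiles of intermediate level rose by 15 points and 100 by 30.

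Mean methylation per library weighted each common position equally, and its 13 comparisons were tested with two-sided exact permutation tests. For the tiles higher or lower in vehicle than in wild type, the set was defined with each vehicle left out in turn. Each vehicle took its level from the set defined without it, and treated libraries their mean over those sets, in 12 exact permutation tests. For comparisons that share controls, unchanged groups were simulated 20 times against the same libraries, and for 5-Aza and the combination the vehicles were also split into odd and even numbers. The simulated groups were drawn around the levels of the shared controls, which leaves out the error of these controls. The spread of a pair of libraries relative to sampling noise is the median Pearson chi-square over tiles divided by its expected median. The disagreement of the 2 strands of a CpG was measured in the same way, over those of 8423 CpGs with a level of 20 to 80% over all libraries that lay between 10 and 90% in the library. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

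The gene table at hand belongs to another assembly than mm9, so regions are given by mm9 coordinates, and the tests of promoters and gene lists and the split of mean methylation by promoter, exon and intron were not run. By the rule for this case, the named tiles were the 5 largest rises and 5 largest falls among called tiles whose replicate ranges did not overlap, or 4 and 4 for a combination against a single drug. Regions of at least 3 neighbouring called tiles, and values of named tiles in further groups, were chosen after their values were seen. Region levels pool the reads of all tested tiles inside them. A CpG was taken to read as a strain variant when it was at 10% or less in at least 2 libraries whose neighbours in the tile averaged at least 60%, and at 60% or more in at least 2 libraries. For the tiles called between IDH2 and TET2 vehicle, the difference was also taken without the CpG that differed most in the direction of the call, chosen after seeing the data and tested on simulated tiles. Chosen after seeing the data too, the tiles lower under 5-Aza against the vehicles of its prefix were followed in other groups, as the change from vehicle minus that at tiles in the same 2-point bin of vehicle level that 5-Aza moved by under 5 points. For the TET2 combination these were the 4 vehicles not used to choose the tiles. The other settings were a coverage minimum of 20, tiles of 500 bp, at least 5 positions per tile, positions common to the 2 groups, limma on M values, a spread from all 9 groups, the replicate number as a block, vehicles of 1 prefix, reads weighted equally, positions under the 99.9th percentile of coverage, genotype tiles of at least 25 points or defined with all vehicles, and leaving out each library. Added after seeing the data were vehicles with Y coverage, a sex term, coverage capped at 20 reads, removal of strain-like positions, and the samples of the block fit without the block.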

Results

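DNA methylation was measured by enhanced reduced representation bisulfite sequencing, an assay that reads cytosine methylation at CpG-rich sites cut by a restriction enzyme, in 35 libraries of mouse LSK cells, the lineage-negative, Sca-1 and Kit positive fraction that holds haematopoietic stem and progenitor cells. The libraries fell into 9 groups. Wild type had 3 libraries. Mice with mutant Idh2 and the Flt3 internal tandem duplication (IDH2 mutant below) had 4 vehicle libraries, 3 under AC220, 4 under AG-221 and 3 under both drugs. Mice lacking Tet2 with the same Flt3 change (TET2 mutant below) had 6 vehicle libraries, 4 under AC220, 4 under 5-azacytidine (5-Aza) and 4 under AC220 with 5-Aza. AC220 (quizartinib) inhibits FLT3, AG-221 (enasidenib) inhibits mutant IDH2, and 5-Aza is a nucleoside analogue that traps DNA methyltransferases. AC220 was given at 10 mg/kg, and 5-Aza at 5 mg/kg on 5 days of each 21-day cycle for 4 cycles. AG-221 was given 2 times a day at 100 mg/kg alone but at 40 mg/kg in the combination, so the combination differs from the single drug in dose as well. The libraries held 1466807 to 2142633 CpG positions at a median coverage of 55 to 131 reads, and 1101719 autosomal positions were covered at least 10 times in all 35. These made 78870 tiles of 1 kb, each with a median of 5 CpG positions and 567 reads per library.

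**Figure D1:**
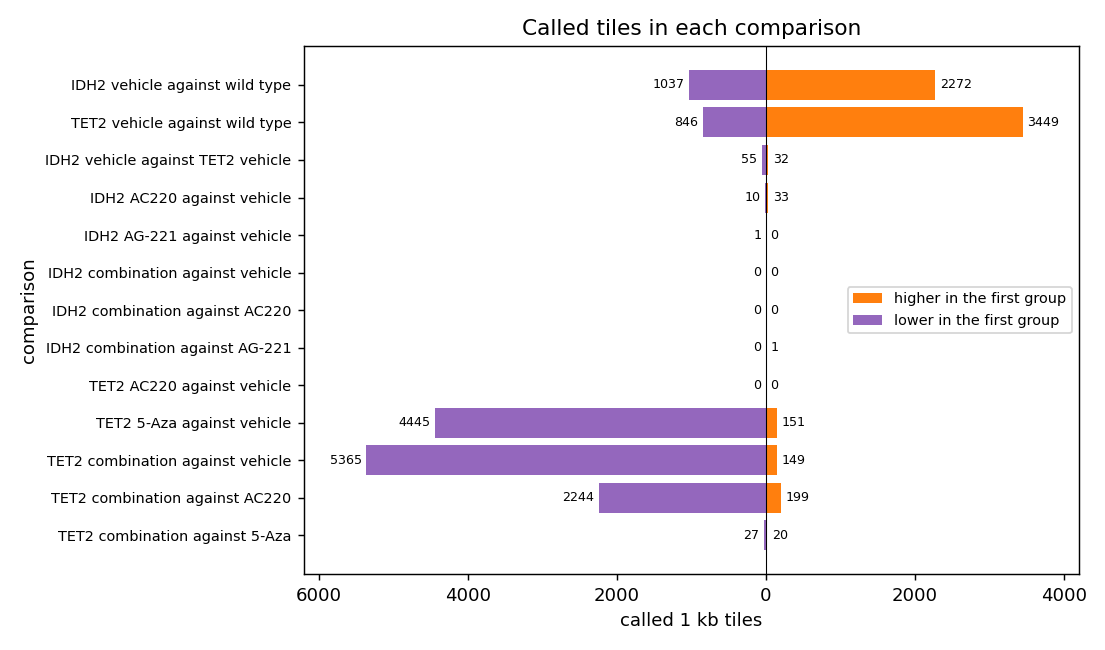
Number of 1 kb tiles (x axis) called higher (right) or lower (left) in the first-named group of each comparison (y axis), out of 78870 tested. The longest bars are the 5365 tiles lower under the combination and the 4445 lower under 5-Aza in TET2 mutant libraries, and the 3449 higher in TET2 vehicle than in wild type.

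IDH2 mutant vehicle against wild type asks what the leukaemic genotype changes in this compartment. Methylation was higher in 2272 tiles and lower in 1037. Of these, 118 higher and 42 lower tiles held a position that reads as a strain variant, as did 1.32% of all tiles. The largest rise lay on chromosome 8, 113494001 to 113495000, at 92.8% ± 1.59 (SD, n = 4) in IDH2 vehicle and 8.03% ± 1.95 (SD, n = 3) in wild type. Rises of over 60 points were also found on chromosome 12, 42041001 to 42042000 (86.7% against 19.3%), and on chromosome 8, 87308001 to 87309000 (88.1% against 21.0%). The largest fall lay on chromosome 10, 94873001 to 94874000, at 3.04% ± 3.28 (SD, n = 4) against 94.9% ± 0.294 (SD, n = 3), followed by chromosome 8, 125922001 to 125923000 (7.98% against 91.8%) and chromosome 12, 25462001 to 25463000 (13.4% against 92.9%). Of 55879 tiles with 3 to 9 common CpG positions 1649 rose and 907 fell, and of 13356 with 10 to 29 positions 534 and 126. Of 9635 with at least 30, 89 (0.924%) rose and 4 fell. Positions in these densest tiles averaged 1.58% in wild type, so few such tiles could fall by the 10 points a call needs. By the quasi-binomial test moderated with limma, the adjusted p of the 5 largest rises and 5 largest falls ranged from 8.65e-07 to 0.000255. Mean methylation over all common positions was 28.8% ± 0.393 (SD, n = 4) against 28.1% ± 0.222 (SD, n = 3), a difference of 0.703 points that did not pass the two-sided exact permutation test (p = 0.0857, adjusted p = 0.186 over 13 comparisons), and with reads weighted equally the direction turned, to -4.67 points (exact permutation adjusted p = 0.557). limma on M values called 703 higher and 405 lower, and with each CpG capped at 20 reads, a choice made after seeing the data, 1359 were higher and 622 lower. The counts fell to 1295 higher and 573 lower without wild type replicate 2, and to 1127 and 578 without replicate 3. All wild type files carry a prefix of their own in their names, so no comparison with wild type within 1 prefix could be made.

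TET2 mutant vehicle against wild type gave 3449 higher and 846 lower tiles. Of these, 186 higher and 44 lower tiles held a position that reads as a strain variant, as did 1.32% of all tiles. The same tile of chromosome 8, 113494001 to 113495000, led the rises at 92.4% ± 3.43 (SD, n = 6) against 8.03% ± 1.95 (SD, n = 3). Chromosome 11, 102824001 to 102825000, rose from 15.8% to 81.4%, and chromosome 6, 136907001 to 136908000, from 29.3% to 91.8%. The falls were led by chromosome 10, 94873001 to 94874000 (3.44% against 94.9%), and by a pair of neighbouring tiles on chromosome 9, 107202001 to 107204000, at 4.17% and 10.7% against 93.5% and 96.8%. Mean methylation was 29.1% ± 0.275 (SD, n = 6) in TET2 vehicle, 1.02 points above wild type, the smallest p the design can give in a two-sided exact permutation test (p = 0.0119) but not past the threshold over 13 comparisons (adjusted p = 0.0516). With reads weighted equally the direction turned, to -3.34 points (exact permutation p = 0.0357, adjusted p = 0.464). limma on M values called 1866 higher and 481 lower, a spread taken from all 9 groups gave 2168 higher, and without wild type replicate 3 the higher tiles numbered 2295. Against wild type, the 4 vehicles of one prefix had 3276 higher and 773 lower tiles, and the 2 of the other 4155 and 1168.

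Many tiles moved alike in both genotypes. Of the tiles higher in IDH2 vehicle, 1693 (74.5%) were also higher in TET2 vehicle, where independent lists would share 99.4. Of the lower tiles 547 (52.7%) were shared, where independent lists would share 11.1, and 3 tiles moved in opposite directions. Unchanged groups simulated against the same 3 wild type libraries shared 0 tiles, a value without any effect that does not apply to lists of this length. Over all 78870 tiles the differences from wild type had a covariance of 30.9, against 0.180 in the simulation, and r = 0.815 against 0.0443. The simulation drew the groups around the levels of these wild type libraries. It thus leaves out the error of the shared controls and gives no measure of their part. With only 3 wild type libraries these could not be split, so part of the excess may come from the shared controls. The longest shared region was chromosome 11, 57640001 to 57647000, where its 6 tested tiles together stood at 11.3% ± 0.590 (SD, n = 3) in wild type, 29.9% ± 5.49 (SD, n = 4) in IDH2 vehicle and 35.2% ± 3.98 (SD, n = 6) in TET2 vehicle. On chromosome 5, 144014001 to 144018000, the 4 tiles stood at 8.84% ± 0.986 in wild type, 48.9% ± 7.89 in IDH2 vehicle and 48.1% ± 16.2 in TET2 vehicle (SD, same n).

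IDH2 vehicle against TET2 vehicle, the genotypes set side by side, gave 32 higher and 55 lower tiles, in groups of different file name prefixes. Chromosome 17, 45654001 to 45655000, was lower in IDH2 vehicle at 25.6% ± 9.06 (SD, n = 4) against 71.0% ± 6.88 (SD, n = 6), and wild type was 78.8% there. Chromosome 14, 47600001 to 47601000, stood at 18.3% against 57.8%. The largest rise was chromosome 3, 127509001 to 127510000, at 96.6% ± 1.86 against 56.2% ± 12.6 (SD, same n). That tile holds a position that reads as a strain variant, and so do 26 of the 32 higher tiles and 3 of the 55 lower ones, against 1.32% of all tiles. Without such positions, a choice made after seeing the data, 3 tiles were higher and 38 lower. The 17 lower tiles lost there held no such position and kept their difference, and missed the threshold by the quasi-binomial test with limma moderation (adjusted p = 0.0501 to 0.0611). limma on M values called 22 higher and 14 lower, which turns the balance of the directions. Mean methylation differed by -0.315 points (two-sided exact permutation p = 0.176, adjusted p = 0.286 over 13 comparisons), by -1.33 with reads weighted equally, and by -0.129 without IDH2 vehicle replicate 1. The higher count lay between 14 and 20 without IDH2 vehicle replicate 2, 3 or 4 or TET2 vehicle replicate 1 or 6, and the lower count was 29 without TET2 vehicle replicate 1 and 34 without replicate 6.

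**Figure D2:**
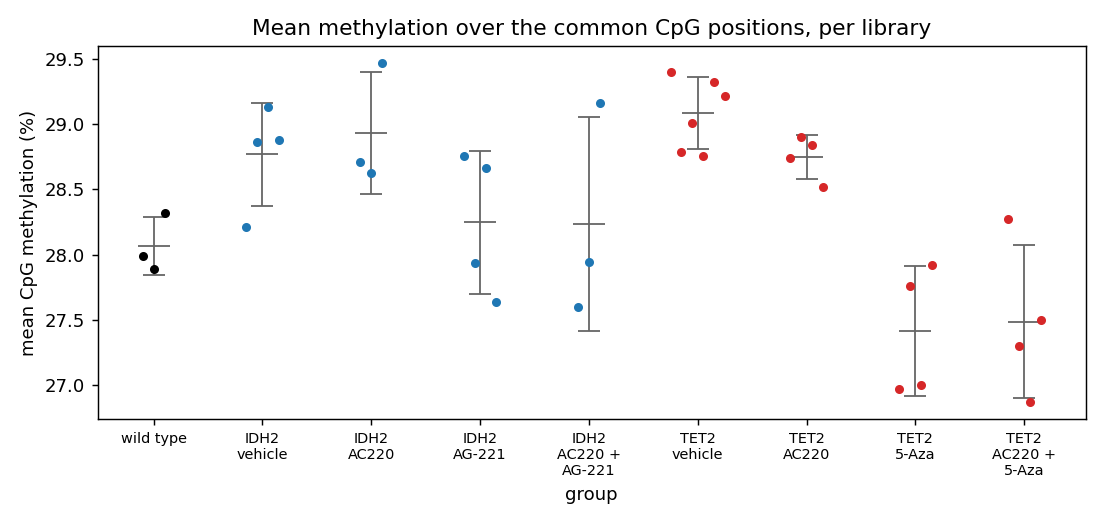
Mean CpG methylation (y axis, percent) over the 1101719 common positions in each of 35 libraries (points) by group (x axis), with the group mean and SD as the grey bar. The TET2 mutant 5-Aza libraries have a mean of 27.4% and the combination libraries 27.5%, against 29.1% in their vehicles.

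IDH2 mutant AC220 against vehicle gave 33 higher and 10 lower tiles. The largest rises were chromosome 4, 133716001 to 133717000, at 81.2% ± 12.7 (SD, n = 3) against 2.95% ± 1.09 (SD, n = 4), and chromosome 9, 21992001 to 21993000, at 80.9% ± 8.79 against 20.8% ± 4.37 (SD, same n). The largest falls were chromosome 15, 79749001 to 79750000 (73.1% against 98.1%), and chromosome 10, 76812001 to 76813000 (68.7% against 93.2%). The combination libraries, which share the AC220 file name prefix, stood at 53.6%, 49.3%, 78.0% and 61.5% in these 4 tiles. Mean methylation differed by 0.166 points (two-sided exact permutation p = 0.686, adjusted p = 0.810), and by 1.22 with reads weighted equally. The direction turned without AC220 replicate 3 (-0.102 points) or vehicle replicate 1 (-0.0209). Drug and prefix cannot be told apart here, since no vehicle shares the prefix of the AC220 libraries. These libraries also lack the chromosome Y coverage that the vehicles have. In the TET2 mutant libraries of 1 prefix, 4 libraries without Y coverage against 4 with it gave 9 higher tiles and 0 lower by the quasi-binomial test (4982 at an unadjusted p under 0.05). Of the 43 tiles 5 were called there too, out of the 9 called among all tested tiles. In all, 11 of the 43 had an unadjusted p under 0.05 there in the direction of their call. Among all tiles 6.32% had such a p in either direction. The 43 differed in the direction of their call by a median of 0.599 points there (quartiles -1.50 to 3.64), against 19.9 points under AC220. Differences that go with Y coverage are thus not set aside for part of these tiles. Leaving out AC220 replicate 1 or 3 left 20 or 19 higher tiles, and the lower tiles numbered 2 to 4 without AC220 replicate 2 or 3 or vehicle replicate 2, 3 or 4. limma on M values called 4 higher and 1 lower, and a spread taken from all 9 groups gave 67 and 62.

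IDH2 AG-221 against vehicle, all 8 libraries from files of 1 prefix, gave 0 higher tiles and 1 lower. That tile, chromosome 14, 51512001 to 51513000, stood at 5.88% ± 1.13 (SD, n = 4) under AG-221 and 34.9% ± 3.96 (SD, n = 4) in vehicle (adjusted p = 0.0171, quasi-binomial test with limma moderation). Whatever the test, 2884 tiles were at least 10 points lower and 573 at least 10 points higher. The same test counted 5742 tiles (7.28%) at an unadjusted p under 0.05, and limma on M values called 0 higher and 0 lower. The tile missed the threshold without any 1 of the 8 libraries (differences of -30.2 to -27.3 points). The lower count was 0 without AG-221 replicate 1, 2 or 3 or any vehicle, and the 1 tile lower without AG-221 replicate 4 was another one. Mean methylation was 28.2% ± 0.547 (SD, n = 4) against 28.8% ± 0.393 (SD, n = 4), a difference of -0.520 points (two-sided exact permutation p = 0.171, adjusted p = 0.286), -1.72 with reads weighted equally and -0.317 without AG-221 replicate 4. In simulated libraries with this spread, 46 of 100 tiles changed by 30 points were called, 6 of 100 changed by 15, and 5 unchanged tiles. A spread taken from all 9 groups gave 5 lower tiles.

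The IDH2 mutant combination gave 0 higher and 0 lower tiles against vehicle, 0 and 0 against AC220, and 1 higher and 0 lower in IDH2 combination against AG-221. That tile, chromosome 19, 41675001 to 41676000, stood at 37.5% ± 6.38 (SD, n = 3) in the combination and 7.47% ± 2.44 (SD, n = 4) under AG-221. The chromosome 8 tile that led the rises of both genotypes, 113494001 to 113495000, stood at 60.3% ± 23.1 (SD, n = 3) in the combination, 82.5% ± 12.8 (SD, n = 3) under AC220 and 79.8% ± 14.1 (SD, n = 4) under AG-221, with no call. The spread between pairs of the 3 combination libraries had a median of 22.5 times sampling noise, the highest of the 9 groups, against 5.12 for the IDH2 vehicles. The quasi-binomial test counted 10023, 6596 and 8912 tiles at an unadjusted p under 0.05, and limma on M values called 0 in each of the 3 comparisons. A spread taken from all 9 groups, planned as an alternative, gave 290 higher and 2018 lower against vehicle, 245 and 1555 against AC220, and 502 and 1220 against AG-221. In simulated libraries with this spread, 22 of 100 tiles changed by 30 points were called against vehicle, 33 against AC220 and 14 against AG-221, so many changes of that size were not detectable here. Without combination replicate 3, 18 tiles were higher and 86 lower than in vehicle, 7 and 199 than under AC220, and 10 and 13 than under AG-221. Without replicate 1, 3 tiles were higher and 3 lower than in vehicle, and 1 was lower than under each single drug. The tile on chromosome 19 missed the threshold without combination replicate 1 or 2 or any 1 of the AG-221 libraries (differences of 26.9 to 30.8 points), and in libraries simulated for that comparison 1 unchanged tile was called. Mean methylation was 28.2% ± 0.822 (SD, n = 3), and its differences of -0.537, -0.702 and -0.0162 points from vehicle, AC220 and AG-221 did not pass (two-sided exact permutation p = 0.314, 0.300 and 0.943, adjusted p = 0.409, 0.409 and 0.943). With reads weighted equally the last 2 were -1.64 and 1.30 points. Without combination replicate 1 they were -0.218, -0.384 and 0.302 points, and without replicate 3 -1.0002, -1.17 and -0.480. Against AC220 the difference was -0.434 points without AC220 replicate 3. The direction against AG-221 also turned without combination replicate 2 (0.129 points) or AG-221 replicate 1 or 3 (0.153 and 0.121). The comparison with AC220 cannot go below p = 0.1 in an exact test. The combination shares its file name prefix with AC220 only. It also lacks the chromosome Y coverage (20 to 108 positions) of the vehicle (347 to 387) and AG-221 libraries (314 to 403). Against vehicle and AG-221, drug, prefix and Y coverage thus cannot be told apart.

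TET2 mutant AC220 against vehicle gave 0 higher and 0 lower tiles by the quasi-binomial test and by limma on M values, and 4560 tiles (5.78%) at an unadjusted p under 0.05. In simulated libraries with this spread, 74 of 100 tiles changed by 30 points and 26 of 100 changed by 15 were called. Mean methylation was 28.8% ± 0.169 (SD, n = 4) against 29.1% ± 0.275 (SD, n = 6), a difference of -0.334 points (two-sided exact permutation p = 0.0714, adjusted p = 0.186), which turned to 0.111 points with reads weighted equally. Without AC220 replicate 1 there was 1 higher tile, and without vehicle replicate 3 there was 1 lower tile. With AC220 replicate 3 and vehicle replicate 3 exchanged, the highest of 100 splits of these libraries, 515 tiles were called. Whether the effect of AC220 differed between the genotypes was tested on mean methylation and on the tiles higher or lower than in wild type, and none of the 3 exact permutation tests passed (p = 0.170, 0.477 and 0.842, adjusted p = 0.509, 0.716 and 0.842). In the tests on tiles each genotype was measured on its own set, so they compare effects on sets that differ. Per tile, a limma interaction term on M values called 12 tiles (smallest adjusted p = 0.00168), with genotype and prefix confounded.

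Under 5-Aza, methylation fell widely in TET2 mutant libraries: 4445 tiles were lower than in vehicle and 151 higher. Chromosome 4, 11633001 to 11634000, fell from 96.0% ± 1.62 (SD, n = 6) to 15.2% ± 14.6 (SD, n = 4), chromosome 17, 88145001 to 88146000, from 70.3% to 3.46%, and chromosome 10, 98728001 to 98729000, from 68.9% to 7.87%. Classed by the level in the TET2 AC220 libraries, which are in neither group, 22.7% of the tiles between 20 and 80% fell, 4.69% of those over 80% and 0.793% of those at 20% or less, a classing chosen after seeing the data. A call needs a fall of at least 10 points, which tiles under 10% in vehicle cannot show. The rises were led by chromosome 9, 107203001 to 107204000, from 10.7% ± 4.12 (SD, n = 6) to 69.7% ± 16.2 (SD, n = 4), a tile at 96.8% in wild type, and by chromosome 7, 152118001 to 152119000, from 3.60% to 60.03%, a tile at 17.5% in wild type. Mean methylation was 27.4% ± 0.500 (SD, n = 4) against 29.1% ± 0.275 (SD, n = 6), lower in 4 of 4 libraries than in any vehicle (two-sided exact permutation p = 0.00476, the smallest the design can give, adjusted p = 0.0310). With reads weighted equally the difference was -1.16 points (exact permutation adjusted p = 0.784), and without any 1 of the 10 libraries it lay between -1.84 and -1.52 points (exact permutation adjusted p = 0.0516, a bound of the smaller design). The difference was -3.57 points at positions in tiles with 3 to 9 common CpG positions (exact permutation adjusted p = 0.0310) and -0.382 points in tiles with 30 or more (exact permutation adjusted p = 0.0619). Vehicles stood at 73.9% in the former and at 2.10% in the latter, where little room was left to fall. Against the 2 vehicles that share the 5-Aza file name prefix, 650 tiles were lower and 49 higher. Without 5-Aza replicate 3 the higher tiles numbered 78. limma on M values called 2419 lower and 80 higher.

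The TET2 mutant combination gave 5365 lower and 149 higher tiles than vehicle. Pairs of its 4 libraries differed by a median of 14.3 times sampling noise, against 4.10 for the TET2 vehicles. The 2 strands of a CpG disagreed by 7.83 to 51.1 times sampling noise in these libraries, against 3.26 to 9.16 in the vehicles. Chromosome 7, 74588001 to 74589000, fell from 86.5% ± 7.41 (SD, n = 6) to 11.3% ± 6.25 (SD, n = 4), and chromosome 10, 127098001 to 127099000, from 86.3% to 28.2%. The region of chromosome 5, 144014001 to 144018000, stood at 3.93% ± 1.23 (SD, n = 4), below wild type at 8.84%, and at 11.5% ± 14.2 (SD, n = 4) under 5-Aza. Chromosome 7, 152118001 to 152119000, rose as under 5-Aza, from 3.60% to 61.7%. Of the tiles lower under 5-Aza 2737 (61.6%) were also lower here, where independent lists would share 302. Simulated unchanged groups shared 0, again without any effect. With the vehicles split, the lists shared 503 and 517 tiles, against 29.03 and 34.1. The covariance of the 2 effects was 26.6, and 24.5 and 23.6 with split vehicles, against 0.156 in the simulation. The simulation was drawn around the levels of the shared vehicles and so leaves out their error, while split vehicles are not shared. Mean methylation was 27.5% ± 0.588 (SD, n = 4), a difference of -1.60 points from vehicle in 4 of 4 libraries (two-sided exact permutation p = 0.00476, adjusted p = 0.0310). It was -1.10 points with reads weighted equally (exact permutation adjusted p = 0.836) and -1.86 to -1.39 points without any 1 of the 10 libraries (exact permutation adjusted p = 0.0516, a bound of the smaller design). No vehicle shares the prefix of the combination. At the 650 tiles lower under 5-Aza against vehicles of its own prefix, the combination differed from the 4 other vehicles by -20.8 points, against -3.84 at tiles matched on their level. The IDH2 combination, without 5-Aza, differed from its vehicles by -7.87 and -1.69 points in a matching of the same kind. Against the 4 vehicles of one prefix 3176 tiles were lower and 68 higher, against the 2 of the other 700 and 34, and against vehicles with Y coverage 3391 and 85. limma on M values called 3053 lower and 61 higher. Without vehicle replicate 6 there were 95 higher tiles.

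The TET2 mutant combination against AC220, which asks what 5-Aza adds, gave 2244 lower and 199 higher tiles. The groups carry different file name prefixes, and AC220 shares that of 4 vehicles. At the 650 tiles lower under 5-Aza within its prefix, AC220 differed from these 4 vehicles by -3.31 points, against -0.239 at matched tiles, where the combination differed by -20.8 and -3.84. Chromosome 4, 11633001 to 11634000, stood at 39.6% ± 8.37 (SD, n = 4) against 97.2% ± 1.88 (SD, n = 4), and chromosome 5, 125082001 to 125083000, at 91.1% ± 1.87 against 33.5% ± 26.3 (SD, same n). Mean methylation differed by -1.27 points (two-sided exact permutation p = 0.0286, the smallest possible, adjusted p = 0.0929). These counts rested on single libraries: the lower tiles numbered 432, 437 and 788 and the higher 28, 22 and 50 without AC220 replicate 1, 2 or 4, and the lower 4009 and 1435 without combination replicate 1 or 3. limma on M values called 15 lower and 2 higher, and a spread taken from all 9 groups gave 3773 and 337. The combination against 5-Aza, which asks what AC220 adds, gave 27 lower and 20 higher tiles, such as chromosome 13, 55941001 to 55942000 (29.3% ± 7.19 against 74.2% ± 6.79, SD, n = 4 each), and chromosome 5, 23770001 to 23771000 (85.4% against 40.4%), a tile with a position that reads as a strain variant. Here too the prefixes differ, and drug and prefix cannot be told apart. Without any 1 of the 4 5-Aza libraries or combination replicate 2, 3 or 4 the higher tiles numbered 4 to 10 and the lower 3 to 13, and limma on M values called 0 and 0 (6641 tiles at an unadjusted p under 0.05 in the quasi-binomial test), while a spread taken from all 9 groups gave 62 higher and 57 lower. Mean methylation differed by 0.0725 points (two-sided exact permutation p = 0.914, adjusted p = 0.943), and the direction turned without combination replicate 1 (-0.190 points) or 5-Aza replicate 1 or 3 (-0.0760 and -0.0651).

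Whether the drugs moved methylation of the genotype tiles towards wild type was measured with each vehicle left out of the set it was measured on. The wild type libraries were not left out of the choice of tiles, which may widen the gap that the shares below rest on. In the tiles higher in TET2 vehicle than in wild type, the level was 63.9% ± 2.72 (SD, n = 6) in vehicle and 44.8% ± 1.36 (SD, n = 3) in wild type. It was 50.7% ± 4.10 (SD, n = 4) under 5-Aza, closing 69.1% of the gap, and 47.4% ± 4.13 (SD, n = 4) under the combination, closing 86.6%, both lower in 4 of 4 libraries (two-sided exact permutation p = 0.00476, adjusted p = 0.0286 over 12 tests). Without 1 treated library the changes were -14.9 to -11.7 points under 5-Aza and -17.9 to -14.8 under the combination, and each of the 8 such exact permutation tests missed the threshold (adjusted p = 0.0714). Under AC220 it was 60.3% ± 1.94 (SD, n = 4), 18.9% of the gap (exact permutation p = 0.0476, adjusted p = 0.190). In the tiles lower in TET2 vehicle, the level was 38.3% ± 1.96 (SD, n = 6) in vehicle, 59.2% ± 1.38 (SD, n = 3) in wild type, 37.8% ± 1.43 (SD, n = 4) under 5-Aza and 38.2% ± 2.78 (SD, n = 4) under the combination, and neither difference passed (exact permutation p = 0.695 and 0.910, adjusted p = 0.810 and 0.910). In the tiles higher in IDH2 vehicle, at 62.2% ± 4.46 (SD, n = 4) against 43.3% ± 1.23 (SD, n = 3) in wild type, the level was 61.0% ± 2.16 (SD, n = 3) under AC220, 57.2% ± 4.52 (SD, n = 4) under AG-221 and 56.1% ± 6.19 (SD, n = 3) under the combination. These close 6.17%, 26.6% and 32.4% of the gap, and none passed (exact permutation p = 0.743, 0.171 and 0.171, adjusted p = 0.810, 0.343 and 0.343). With sets defined by all vehicles the AC220 share was 14.2%, and in sets of at least 25 points 9.54%. Single libraries moved these shares: to 3.17, 2.57 and 12.8% without AC220 replicate 1, 2 and 3, to 17.6% without AG-221 replicate 4, and to 21.4 and 51.3% without combination replicate 1 and 3, and none passed. The tiles lower in IDH2 vehicle stood at 42.6% ± 2.20 (SD, n = 4) there and 63.4% ± 1.12 (SD, n = 3) in wild type. They stood at 43.6% under AC220, 39.1% under AG-221 and 41.0% under the combination, closing 4.70%, -16.8% and -7.76% of the gap. The last 2 thus lay further from wild type than vehicle, and none passed (exact permutation p = 0.543, 0.114 and 0.429, adjusted p = 0.810, 0.343 and 0.735). Against the 2 vehicles of its own prefix, 5-Aza differed by -14.7 points in the higher TET2 tiles, which 2 vehicles against 4 cannot bring past the threshold (exact permutation adjusted p = 0.257). The combination did not differ from 5-Aza in the higher tiles past the threshold (-3.34 points, exact permutation p = 0.343, adjusted p = 0.777 over 8 tests), and its difference from AC220 of -12.9 points (exact permutation p = 0.0286) did not pass over 8 tests (adjusted p = 0.229).

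**Figure D3:**
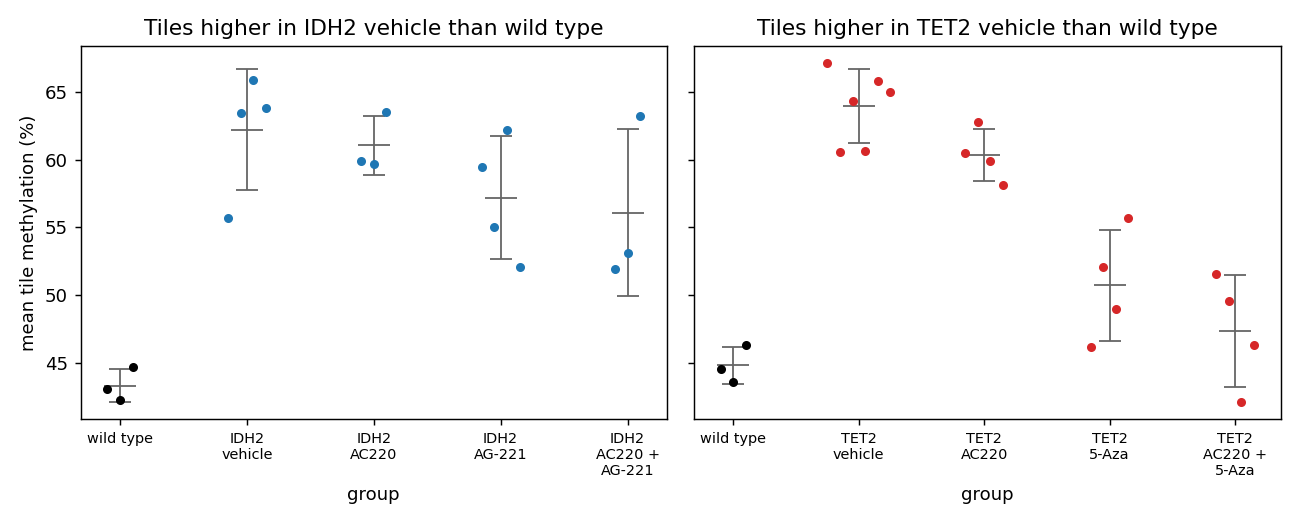
Mean methylation (y axis, percent) of the tiles higher in IDH2 vehicle (left) or TET2 vehicle (right) than in wild type, per library (points) and group (x axis), with the group mean and SD as the grey bar. Each vehicle is measured on tiles chosen without it; the 5-Aza and combination libraries have means of 50.7% and 47.4%, between the TET2 vehicles at 63.9% and wild type at 44.8%.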

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

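The test of few molecules was set before its result was seen, and the other tests weighed below were chosen only after the result was seen.

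The fall of methylation under 5-Aza and under the combination in TET2 mutant libraries was weighed against batch, conversion and the mix of cells, and batch is argued against for 5-Aza, where 93.0% of the tiles called against the 2 vehicles of the same prefix were lower. For the combination, whose prefix no vehicle shares, batch is argued against as the whole cause: at the 650 tiles lower under 5-Aza within its prefix, its change from the 4 other vehicles was -17.0 points beyond that at matched tiles (-19.8 to -15.3 in 4 libraries), against -3.07 (lowest -5.35) under TET2 AC220, of the same prefix as these vehicles, and -1.63 (lowest -2.61) under IDH2 AC220 and -6.18 (lowest -9.98) in the IDH2 combination, which also differ from their vehicles in prefix but had no 5-Aza. More complete bisulfite conversion would lower mitochondrial methylation. That averaged only 0.244% in the TET2 vehicles (highest 0.436%). If other DNA converted like mitochondrial DNA, only about that share of reads was left for better conversion to remove. The higher genotype tiles changed by -13.2 points under 5-Aza and -16.6 under the combination. In mitochondrial methylation, treated minus vehicle was 0.289 points for 5-Aza and 1.08 points for the combination, both upward. The 5-Aza libraries (0.439 to 0.654%) also lay above the vehicles of their own prefix (0.381 and 0.436%). On that assumption, these values argue against more complete conversion as the cause of either fall. A larger share of cells with a wild type profile, with no other change, would close the gap alike at both sets of genotype tiles. Instead -2.41% and -0.682% was closed at the tiles lower in vehicle against 69.1% and 86.6% at the higher ones, and in sets of at least 25 points 12.7% and 12.2% against 61.6% and 79.5%. Other tiles, matched to the higher ones on vehicle level, also changed, by -5.97 and -6.06 points. Such a fall at the lower tiles could hide a rise, so these values argue against the mix of cells only as the whole cause. The drug stays a candidate explanation for both falls, as a hypothesis. A part from batch stays open for the combination, and a part from the mix of cells for both falls.

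The 3 IDH2 mutant combination libraries differed widely from one another, and no tile was called between them and vehicle. A single library apart is argued against for the spread, since the closest pair differed by 21.5 times sampling noise and the IDH2 vehicle pairs by 4.44 to 5.68. Few molecules behind the reads stay a candidate explanation, since the 2 strands of a CpG disagreed by a median of 28.0 times sampling noise (23.0 to 45.9), against 4.53 to 7.57 in the vehicles. For the lack of calls a single library stays open too, since 104 tiles were called without replicate 3, 6 without replicate 1 and 0 without replicate 2. No biological explanation of the spread was tested.

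The tiles that differed between IDH2 and TET2 vehicle were weighed against strain variants, which read as methylation differences after bisulfite treatment. Of the 32 tiles higher in IDH2 vehicle 26 held a strain-like position and 7 were still 10 points apart without the CpG that differed most, so strain variants are a candidate explanation there. Of the 55 lower tiles 3 held such a position and 36 were still 10 points apart without that CpG, which argues against a variant at 1 CpG for these 36, while for the others strain and genotype cannot be told apart. On chromosome 3, 130000001 to 140000000, the median level of 9 strain-like CpGs was 78.1 to 98.7% in the IDH2 mutant libraries, 0 to 3.31% in the TET2 mutant ones and 0.435, 21.9 and 52.4% in wild type, and Tet2 lies on this chromosome. The genotype itself stays open as the biological explanation.

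Some single libraries stood apart from their group. The strand disagreement was 7.57 times sampling noise in IDH2 vehicle replicate 4 (others 4.53 to 4.96) and 10.2 in IDH2 AG-221 replicate 1 (others 4.95 to 5.39). Mitochondrial methylation was 0.409% in TET2 AC220 replicate 2 (others 0.137 to 0.179%). These are 3 of 30 groups and measures, where chance marks about 1 in 20. The effect of AC220 differed between IDH2 and TET2 mutant libraries at 12 tiles by a limma interaction term on M values (smallest adjusted p = 0.00168, 8402 tiles at an unadjusted p under 0.05), where genotype and prefix are confounded. In the IDH2 mutant libraries AC220 and vehicle also differ in Y coverage. Mitochondrial methylation, outside the comparisons, lay above the highest wild type library (0.169%) in every library of IDH2 vehicle (mean 0.298%), IDH2 AC220 (1.22%), IDH2 AG-221 (0.412%), the IDH2 combination (1.11%), TET2 5-Aza (0.533%) and the TET2 combination (1.32%). TET2 vehicle and TET2 AC220 also averaged above it (0.244 and 0.216%), with single libraries down to 0.135 and 0.137%. These levels also went with the file name prefix. Without any drug, TET2 vehicle replicates 1 to 4 stood at 0.135 to 0.193%, and replicates 5 and 6, of the 5-Aza prefix, at 0.381 and 0.436%. The highest means by prefix were 1.16% for IDH2 AC220 with the IDH2 combination and 1.32% for the TET2 combination. Prefix, genotype and drug were not separated here.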

How the results depend on the processing

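Chosen after the data were seen were the cap on coverage, the removal of strain-like positions, the vehicles with Y coverage, the sex term and the samples of the block fit without the block; the other settings were planned. Counts of called tiles stayed within 1.5 times in 309 of 474 results and settings. Mean methylation kept its direction and side of the threshold, or moved by less than the spread, in 129 of 159, changes of genotype tiles in 61 of 72, and named tiles in 871 of 1048, with 175 no longer past the threshold and 2 reversed. Gene list alternatives were not run, since no annotation of mm9 was at hand. Unless a reason is given, the cause was not tested. Tiles held a median of 567 reads per library, and the parts of depth and of the spread between libraries in limiting the calls were not separated. Of 100 simulated rises of 30 points, 14 were called for the IDH2 combination against AG-221, the fewest, 22 for it against vehicle, and 83 for TET2 vehicle against wild type.

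With at least 5 positions per tile, 46456 tiles were tested. IDH2 vehicle against wild type had 540 lower, TET2 vehicle against wild type 2046 higher and 401 lower, IDH2 against TET2 vehicle 10 and 24, and IDH2 AC220 6 lower. TET2 5-Aza had 62 higher and 2106 lower, the TET2 combination 58 and 2897 against vehicle, 86 and 1330 against AC220, and 8 and 11 against 5-Aza.

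limma on M values called 703 higher and 405 lower in IDH2 vehicle and 1866 and 481 in TET2 vehicle against wild type, 22 higher and 14 lower in IDH2 than in TET2 vehicle, and 4 and 1 under IDH2 AC220. It called 0 lower under AG-221 (4759 at an unadjusted p under 0.05) and 0 higher in the IDH2 combination against AG-221 (6961). It called 80 and 2419 under 5-Aza, 61 and 3053 for the TET2 combination against vehicle, 2 and 15 against AC220, and 0 and 0 against 5-Aza (6160 unadjusted). Genotype tiles shared were 561 higher and 235 lower, and 442 and 176 at 25 points. Of 78 named tiles 51 passed with limma.

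A spread from all 9 groups gave 2168 higher in TET2 vehicle against wild type, 67 and 62 under IDH2 AC220 and 5 lower under AG-221. The IDH2 combination had 290 and 2018 against vehicle, 245 and 1555 against AC220 and 502 and 1220 against AG-221. There the shared spread replaces a median dispersion of 16.3 within the combination by one that includes 1.62 to 10.7 in the other groups. The TET2 combination had 337 and 3773 against AC220 and 62 and 57 against 5-Aza.

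A coverage minimum of 20 left 0 lower under AG-221 (4653 unadjusted), and positions common to the 2 groups 0 (6849 unadjusted). The latter gave 1 lower for the IDH2 combination against AC220 and 0 higher against AG-221 (10289 unadjusted), where 500 bp tiles also gave 0 (9704 unadjusted). Coverage capped at 20 reads gave 1359 and 622 for IDH2 vehicle against wild type. Against 2 vehicles of its prefix 5-Aza had 49 and 650. The TET2 combination had 68 and 3176 against the 4 vehicles of the first prefix, 34 and 700 against the 2 of the second, and 85 and 3391 against vehicles with Y coverage.

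Replicate numbers did not pair the samples: over the 10000 most variable tiles same-numbered libraries correlated at -0.311 to 0.164 in their deviations from group means, the lowest pair of each comparison was at 0.0362 or less, and in none did every library correlate best with its own number. With the replicate block (limma), TET2 vehicle against wild type had 4 higher and 13 lower. IDH2 vehicle against wild type, IDH2 against TET2 vehicle, IDH2 AC220, TET2 5-Aza and the TET2 combination against vehicle, AC220 and 5-Aza had 0 and 0, with 12586, 5466, 9026, 15542, 15983, 14779 and 6053 tiles at an unadjusted p under 0.05. AG-221 had 0 lower (4586) and the IDH2 combination 0 higher against AG-221 (4431). The same samples without the block gave 835 and 363 for IDH2 vehicle and 817 and 274 for TET2 vehicle against wild type, 13 and 13 for IDH2 against TET2 vehicle, and 1 and 0 for IDH2 AC220 (9407 unadjusted). AG-221 had 0 lower (4759) and the IDH2 combination 0 higher against AG-221 (5093). TET2 5-Aza had 31 and 840, and the TET2 combination 11 and 701 against vehicle, 2 and 15 against AC220 and 0 and 0 against 5-Aza (6160). The block uses up degrees of freedom.

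Without strain-like positions, IDH2 vehicle against TET2 vehicle had 3 higher and 38 lower (17 lower tiles were lost with their reads unchanged) and TET2 combination against 5-Aza 12 higher. The named tile of the former on chromosome 3, 137785001 to 137786000, turned to -1.80 points, and that of the latter on chromosome 16, 63062001 to 63063000, to -2.35 points, since the setting removes the position that differed.

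With reads weighted equally, mean methylation differed by -4.67 points in IDH2 and -3.34 in TET2 vehicle against wild type, -1.33 between them, 1.22 under IDH2 AC220, -1.72 under AG-221, -1.64 and 1.30 for the IDH2 combination against AC220 and AG-221, and 0.111 under TET2 AC220. It was -1.16 for 5-Aza and -1.10 for the TET2 combination, neither past the threshold. In the higher TET2 genotype tiles 5-Aza differed by -14.7 points from the 2 vehicles of its prefix, too few to pass. In sets of 25 points the lower tiles differed by 4.45 points under 5-Aza and 4.29 under the combination, and neither passed the exact permutation test (adjusted p = 0.200 and 0.214).

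Leaving out each library gave these ranges, with the libraries that moved a count by over 1.5 times. IDH2 vehicle against wild type had 1127 to 2908 higher and 573 to 1182 lower (1295 and 573 without wild type 2, 1127 and 578 without 3). TET2 vehicle against wild type had 2295 (without wild type 3) to 3570 higher and 588 to 934 lower. IDH2 against TET2 vehicle had 14 to 32 higher (16, 14 and 15 without IDH2 vehicle 2, 3 and 4, 20 and 16 without TET2 vehicle 1 and 6) and 29 to 63 lower (29 and 34 without TET2 vehicle 1 and 6). IDH2 AC220 had 19 to 26 higher (20 and 19 without AC220 1 and 3) and 2 to 9 lower (3 and 4 without AC220 2 and 3, 2 without vehicle 2, 3 or 4). AG-221 had 0 higher and 0 to 1 lower (0 without any library but AG-221 4), with 4751 to 6659 tiles at an unadjusted p under 0.05 in the quasi-binomial test.

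For the IDH2 combination the counts were 0 to 18 higher and 0 to 86 lower against vehicle, 0 to 7 and 0 to 199 against AC220, and 0 to 10 and 0 to 13 against AG-221, each highest without combination 3. Without combination 1 they were 3 and 3 against vehicle and 1 lower against each drug, and against AG-221 0 were higher without combination 2 or any AG-221 library. At an unadjusted p under 0.05 the quasi-binomial test had 6309 to 15327, 3751 to 10845 and 6126 to 14110 tiles in these comparisons. TET2 AC220 had 0 to 1 higher (1 without AC220 1) and 0 to 1 lower (1 without vehicle 3), with 3325 to 5459 unadjusted.

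TET2 5-Aza had 78 (without 5-Aza 3) to 162 higher and 2987 to 5230 lower, and the TET2 combination 95 (without vehicle 6) to 155 and 3923 to 6728. The combination against AC220 had 22 to 251 higher (28, 22 and 50 without AC220 1, 2 and 4) and 432 to 4009 lower (432, 437 and 788 without the same, 4009 and 1435 without combination 1 and 3). Against 5-Aza it had 4 to 20 higher (10, 9 and 7 without combination 2, 3 and 4, 6, 4, 6 and 7 without 5-Aza 1 to 4) and 3 to 27 lower (9, 11 and 13, and 12, 3, 5 and 9). Mean methylation differed by -1.84 to -1.52 points under 5-Aza and -1.86 to -1.39 under the combination, and higher genotype tiles by -14.9 to -11.7 and -17.9 to -14.8. All these missed the threshold, as fewer libraries raise the smallest p.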

Other observations

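The comparison with matched tiles and the splits of the samples were set before their results were seen; the other values were looked at after the data were seen.

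A tile of chromosome 9, 107202001 to 107203000, stood at 93.5% ± 1.01 (SD, n = 3) in wild type, 15.9% ± 8.97 (SD, n = 4) in IDH2 vehicle and 4.17% ± 1.97 (SD, n = 6) in TET2 vehicle. In TET2 mutant libraries it stood at 16.0% ± 14.9 (SD, n = 4) under AC220, 44.5% ± 11.7 (SD, n = 4) under 5-Aza and 36.8% ± 11.1 (SD, n = 4) under the combination. In IDH2 mutant libraries it stood at 3.74% ± 0.655 (SD, n = 4) under AG-221, 48.1% ± 11.3 (SD, n = 3) under AC220 and 36.4% ± 22.4 (SD, n = 3) under the combination. A region of chromosome 10, 5633001 to 5637000, went the other way: 11.3% ± 0.759 (SD, n = 3) in wild type, 60.7% ± 11.9 (SD, n = 4) in IDH2 vehicle and 54.7% ± 13.9 (SD, n = 6) in TET2 vehicle. It stood at 16.6% ± 9.96 (SD, n = 4) under 5-Aza and 13.03% ± 4.50 (SD, n = 4) under the TET2 combination, and at 30.4% ± 15.7 (SD, n = 4) under AG-221 and 26.0% ± 7.31 (SD, n = 3) under the IDH2 combination. Under AC220 it stood at 38.2% ± 4.70 (SD, n = 4) in TET2 and 50.1% ± 10.1 (SD, n = 3) in IDH2 mutant libraries.

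A hypothesis was that 5-Aza, alone or in the combination, lowers methylation more at tiles gained in the TET2 mutant than at other tiles of the same vehicle level. Vehicles stood at 63.9% in the genotype tiles and 65.8% in the matched ones. The change at genotype tiles minus that at matched tiles was -7.25 ± 3.11 points (SD, n = 4) under 5-Aza and -10.5 ± 2.75 points (SD, n = 4) under the combination, beyond 2 points in 4 of 4 libraries each. These values are consistent with the hypothesis. Under AC220 without 5-Aza the difference was -2.87 ± 1.47 points (SD, n = 4), beyond 2 points in 3 of 4 libraries.

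Other splits of the same samples were counted. For IDH2 vehicle against wild type, only the real split gave as many as its 3309 tiles (1 of 35, highest other 895). The same held for TET2 vehicle against wild type (1 of 84, real 4295, highest other 7). It held for IDH2 against TET2 vehicle (1 of 100, real 87, highest other 4). It also held for IDH2 AC220 (1 of 35, real 43, highest other 3) and TET2 5-Aza (1 of 100, real 4596, highest other 2). The TET2 combination gave the same against vehicle (1 of 100, real 5514, highest other 1). So it did against AC220 (1 of 35, real 2443, highest other 2) and 5-Aza (1 of 35, real 47, highest other 4). The real split is among those counted, so 1 is the fewest possible. The shares were not corrected over the comparisons, so they argue against chance in these comparisons but do not exclude it. For AG-221 another split gave more tiles (2 of 35, real 1, highest other 4), so chance is not argued against. For the IDH2 combination against AG-221, 1 of 35 splits gave as many as the real 1 tile (highest other 0), but 1 unchanged tile was also called in libraries simulated for it, so this call is not set apart from chance. With 0 real tiles every split gives as many, so the count says nothing of chance for the IDH2 combination against vehicle (35 of 35, highest other 7) and against AC220 (10 of 10, highest other 1, with splits too few for a share under 0.05) or for TET2 AC220 (100 of 100). In the last, AC220 replicates 1, 2 and 4 with vehicle replicate 3 against the rest gave 515 tiles, which points to a structure of the samples. That split is the real one with AC220 replicate 3 and vehicle replicate 3 exchanged, and whether these libraries were exchanged was not tested. It also largely follows Y coverage, lacking in its AC220 replicates 2 and 4 and vehicle replicate 3, and among the rest in vehicle replicate 4. Split by Y coverage alone, the libraries of 1 prefix among these (4 without it against 4 with it) gave only 9 called tiles. This argues against Y coverage as the main source of the 515, though vehicle replicates 5 and 6 were not in that split.

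Wild type replicate 4 had chromosome Y coverage (498 positions), but 37.0% of its chromosome X positions lay between 20 and 80%. That share was 4.24 to 7.68% in the other libraries with Y coverage and 36.7 to 54.0% in those without. IDH2 combination replicate 3 had a coverage of chromosome 3 of 1.18 relative to its other chromosomes and the other libraries, where the other 34 libraries lay between 0.935 and 1.03, and its 16 windows of 10 Mb lay between 1.06 and 1.26. TET2 combination replicate 1 had a strand disagreement of 51.1 times sampling noise, the highest of the 35 libraries. Of the 43 tiles called under IDH2 AC220, 8 lay on chromosome 12 between 10000001 and 30000000, where their number among all tiles would give 0.220. Strain-like CpGs were also more frequent in this stretch. They made up 0.530% of CpGs from 10000001 to 20000000 and 0.417% from 20000001 to 30000000, against 0.132% in all tiles. Whether this bears on the 8 tiles was not tested.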
